A study of Mus musculus with 2 samples.

How the data were processed

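ChIP-seq of Chx10 was analysed in 1 ChIP library and 1 input library. Per the labels' protocols, Chx10-ESC aggregates were treated with 0.5 µM retinoic acid and 1 µM purmorphamine, an agonist of Sonic hedgehog signalling, for 2 days, and then with doxycycline (2 µg/mL) or vehicle for 2 to 3 days. The labels do not say which of these last treatments the sequenced cells received. Lysates were sonicated, and libraries were prepared with the Illumina TruSeq protocol and read on a HiSeq 2000. Per the submitters' processing notes, CASAVA and Bowtie2 were used and the build was mm9; their versions are not given in the sources used here. The series' design text names MACS for calling peaks and MEME-ChIP and TOMTOM for motifs, also without versions.

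Each library was deposited by the authors as 2 BED files of aligned reads, 1 line per read with no header. Both files of a library held the same reads and differed only in the chromosome names and the order of lines, so 1 was used. The score column of the deposited files holds the mapping quality of each read, from 0 to 42, and the other columns its position and strand; no filter on mapping quality or on copies had been applied, since qualities of 0 and repeated positions are present. Most reads (91.0% in the ChIP, 89.3% in the input) span 101 bp. Read names place both libraries on the same flow cell lane. Reads with a mapping quality under 10 were 22.1% of the ChIP and 18.8% of the input. Positions beyond the chromosome ends of the later mouse build were checked and fit mm9, and coordinates are given in mm9, counted from 1.

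Everything after the aligned reads was computed here with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, with figures from matplotlib 3.10.9. The fragment length was taken from strand cross-correlation of reads with a mapping quality of at least 30. It was 140 bp in the ChIP, where pairs of opposite strand were 2.70 times as frequent as by chance against 1.20 times at a shift of 2000 bp, and 130 bp in the input (1.73 against 1.16 times). Regions were called with a caller written after the model of MACS. At most 1 read per start and strand was kept, reads were extended to 140 bp, and input reads were multiplied by 1.13 to match the ChIP total. In each 10-bp bin, the ChIP pileup was set against the largest of the genome-wide, 1-kb and 10-kb input rates with a one-sided Poisson probability. Bins at 1e-05 or below were joined across gaps of up to 1 fragment length, and regions at least that long were kept. The genome-wide rate, 0.648 reads per fragment length, refers to the 2543 Mb of 1-kb windows with a read, so the smallest pileup that could be called was 7 reads. The probability compares these 2 libraries, not conditions, and only picks regions.

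The caller was tested on simulated libraries with 200 planted regions before use. Of 50 regions planted at each size, it found 1 at 5-fold, 3 at 10-fold, 39 at 20-fold and 50 at 40-fold over the genome-wide rate in 200 bp. Regions planted at 10-fold or less were thus mostly missed in the simulation. This planted fold is another measure than the ratio of ChIP to input reads within 250 bp of the summit given below. It made 3 calls elsewhere, and 3 with the simulated libraries exchanged. Both simulated libraries were drawn from the same input positions with a random shift, so these numbers do not carry over to the real libraries.

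The size of enrichment is the ratio of ChIP to depth-scaled input reads within 250 bp of the summit, with the exact 95% interval of a ratio of 2 Poisson counts (Clopper-Pearson on the share). PCR copies are not independent molecules, so the intervals of counts and of ratios of counts, and the floors, cover counting error only. Where the input had 0 reads, the fold was taken against a floor of 3 input counts, and the lower bound of the exact interval is given beside it. The interval of the median ratio comes from 1000 bootstrap draws of regions. Expected regions per chromosome follow its share of distinct input reads with a mapping quality of at least 10, leaving out chromosome Y and the mitochondrial genome. For the split of both libraries, ratios are of reads summed over regions, within 250 bp of the summit, with the same exact interval, and the control positions were drawn from input reads of the first part. Random positions for spacing were drawn from input reads, as many per chromosome as there were regions, 100 times. Read density was counted in 100-kb bins from distinct reads with a mapping quality of at least 30, relative to the autosomal median, and steps were placed to 10 kb by the best single change of a Poisson rate.

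The named regions were fixed by a rule written before the data were examined: the 10 with the highest ChIP minus scaled input among regions with a ratio of at least 5, and the 10 with the highest lower bound of the ratio, outside chromosome Y, the mitochondrial genome and places where scaled input exceeds 5 times the genome-wide rate. Chains and segments were named after their values were seen. No test between conditions was made, because each group has 1 library.

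Alternatives covered copies of reads, fragment length, the background rate, the probability, the scaling of the input, depth, mapping quality and the windows used. The plan also had nearest genes, promoter, exon and intron classes, fixed gene lists and motif counts, which need a genome and an annotation of mm9. The gene table at hand is of another build (GRCm38.p6), so regions are given by position and these parts were not analysed here.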

Results

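Chx10, a paired-class homeodomain transcription factor of retinal progenitors and of V2a interneurons in the spinal cord, was mapped on chromatin by immunoprecipitation and sequencing (ChIP-seq). The cells were mouse motor neurons derived from Chx10-ESCs, an embryonic stem cell line built on the A172LoxP line. The series held 2 libraries: 1 made from DNA pulled down with a rabbit antibody against Chx10, and 1 input library made without an antibody. The ChIP library had 14115671 aligned reads, of which 11773324 (83.4%) had a distinct start and strand, and the input had 11375425, of which 10463014 (92.0%) were distinct. With 1 library per group there was no replicate check, and no interval given here covers variation between libraries. Each is a 95% interval that covers counting error or, for bootstrap intervals, the spread among regions. Intervals for numbers or shares of regions treat regions as independent, although they lay closer together than random positions, so these may be too narrow.

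The first comparison, ChIP against input, asked where reads pulled down with the Chx10 antibody were enriched in these motor neurons. There was no library from a control antibody or from cells without Chx10. Background binding of the antibody can therefore not be told apart from Chx10 binding, and the regions are called Chx10 regions in this sense. Chx10 reads were enriched at 17025 regions of the mm9 genome, spread over every autosome and chromosome X. The regions were short, with a median length of 180 bp and an interquartile range of 150 to 240 bp, and together covered 3.51 Mb. Within 250 bp of the summit they held a median of 22 distinct ChIP reads against 3 input reads, and the median of the depth-scaled ChIP to input ratio was 7.41 (bootstrap interval over regions 7.11 to 7.55). The interquartile range of the ratio was 4.89 to 13.3. A ratio of at least 5 was reached by 12571 regions (73.8%), the lower bound of the ratio was above 1 in 98.1%, and 1268 regions had 0 input reads near the summit. With the regions without input reads placed at the fold against a floor of 3 input counts, the median ratio was 6.67. All regions together held 3.20% of the distinct ChIP reads and 0.509% of the input reads, a depth-scaled ratio of 6.28 (6.22 to 6.34).

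The background of this comparison was measured by exchanging the libraries, so that the input was searched for regions over the ChIP. The exchange gave 236 regions, or 1.39% of the number called for Chx10. Of these, 56.8% lay on chromosome Y, on the mitochondrial genome or where the background library exceeded 5 times the genome-wide rate. Without such places, an exclusion applied to the exchanged libraries after the data were seen, 16582 regions were left for Chx10 and 102 for the exchange (0.615%). A stricter probability of 1e-08 left 6723 regions for Chx10 and 100 for the exchange, a share of 1.49% that is no lower, and with all copies of reads kept the share was 3.22%. Fewer reads also gave fewer regions, with 6979 and 6874 called when the ChIP reads were split at random into parts of 50%.

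Of the 6979 regions of the first part, 4078 (58.4%) overlapped a region of the second by at least 1 base, with the same input and with copies of one fragment possible in both parts. To measure the enrichment in reads that had no role in the calls, the distinct reads of both libraries were then split at random. The 5456 regions called in the first parts, outside places of high input, had a summed ChIP to input ratio of 10.7 in those parts and of 7.05 (6.91 to 7.19) in the second parts, where 99.2% had more ChIP than scaled input reads. As many random positions drawn from input reads had a ratio of 0.989 (0.961 to 1.02), and 35.1% of them had more ChIP than scaled input reads. Around the summits, the second part of the ChIP held at most 75.4 distinct reads per kb in a 10-bp bin and 3.36 at 750 to 1000 bp. Input reads of the second part, scaled to the same total, numbered 6.25 per kb within 50 bp of the summit and 2.72 per kb at 750 to 1000 bp. Smoothed over 3 bins, the ChIP peak was 160 bp wide at 50% of its height above the background. Plus-strand reads were most frequent 65 to 75 bp before the summit and minus-strand reads 65 to 75 bp after it.

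**Figure D1:**
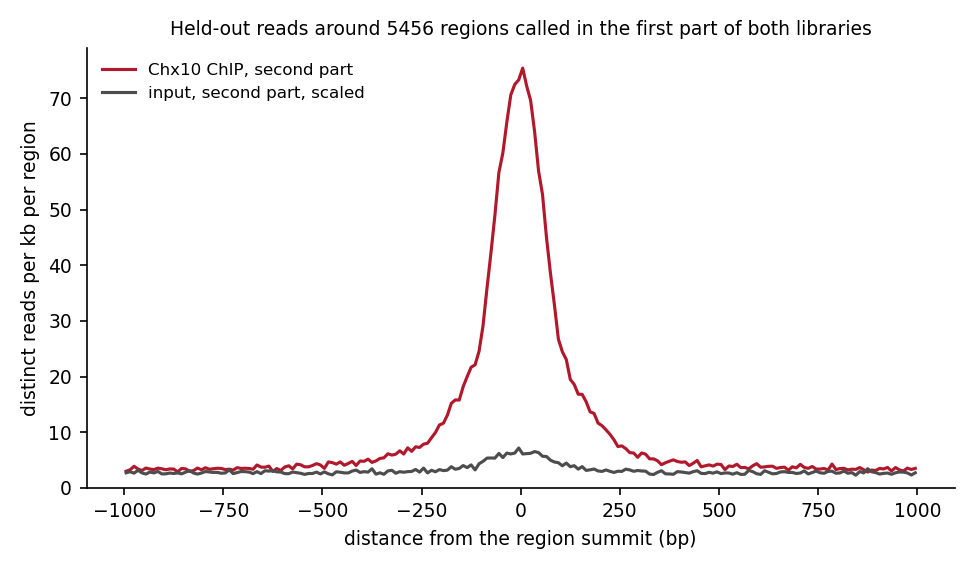
Mean number of distinct reads per kb (vertical axis) by distance in bp from the summit (horizontal axis) for 5456 regions called in the first part of both libraries; the red line gives the second part of the ChIP and the grey line that of the input, scaled to the same total. The ChIP line rises from 3.36 reads per kb at the edges to 75.4 in the highest bin, while the input rises from 2.72 at the edges to 6.25 within 50 bp of the summit.

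The regions with the most Chx10 reads over input were single sites on 9 chromosomes. The highest, on chromosome 4 at 146349481 to 146349880, had 146 distinct ChIP reads against 9 input reads within 250 bp of the summit (ratio 14.4, 7.39 to 32.2), but only 18.7% of the ChIP reads there had a mapping quality of 10 or more, so their placement is uncertain. On chromosome 14, the region from 104277101 to 104277500 had 120 ChIP and 5 input reads (ratio 21.3, 8.89 to 66.9), and that from 102053861 to 102054410 had 114 and 6 (16.9, 7.52 to 47.0); both lie in a segment of raised read density described below. The region of chromosome 1 at 173408261 to 173408600 had 120 ChIP and 9 input reads, a ratio of 11.8 (6.04 to 26.5). A region of chromosome 17 at 30747081 to 30747560 combined 102 ChIP reads with 3 input reads, a ratio of 30.2 (10.1 to 149). The other 5 of these 10 regions lay on chromosome 3 at 96054861 to 96055260, chromosome 9 at 64515581 to 64515940, chromosome 7 at 19886351 to 19886620, chromosome 15 at 12243651 to 12244040 and chromosome 16 at 94670331 to 94670680. Their ratios were 20.1, 14.6, 10.1, 19.2 and 11.1 in that order, and at the last of them 68.2% of the ChIP reads had a mapping quality of 10 or more.

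Regions ranked by the lower bound of their ratio were nearly free of input reads. On chromosome 14 at 99482371 to 99483390, the longest of all regions at 1020 bp and inside the same raised segment, 95 ChIP reads stood against 1 input read, a ratio of 84.4 with a wide interval (14.8 to 3369). The region of chromosome 4 at 19935061 to 19935400 held 64 ChIP reads and 0 input reads, which is 18.96-fold enrichment against the floor of 3 input counts. The lower bound of its exact interval was 14.98, and here and below that bound, not the fold against the floor, is the minimum. On chromosome 6, 57 ChIP reads and 0 input reads at 89294431 to 89294780 gave 16.9-fold against that floor (lower bound 13.3). Chromosome 5 had a region at 29947241 to 29947500 with 55 ChIP reads and 0 input reads (16.3-fold against the floor, lower bound 12.8). Another lay at 112169961 to 112170300 with 53 and 0 (15.7-fold, lower bound 12.3). The remaining 5 also had 0 input reads and between 49 and 53 ChIP reads, giving 14.5-fold to 15.7-fold against the floor, with lower bounds from 11.4 to 12.3. They lay on chromosome 1 at 30865161 to 30865450, chromosome 17 at 41345661 to 41346050, chromosome 3 at 137559191 to 137559600 and at 146101431 to 146101760, and chromosome 4 at 134328811 to 134329190.

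**Figure D2:**
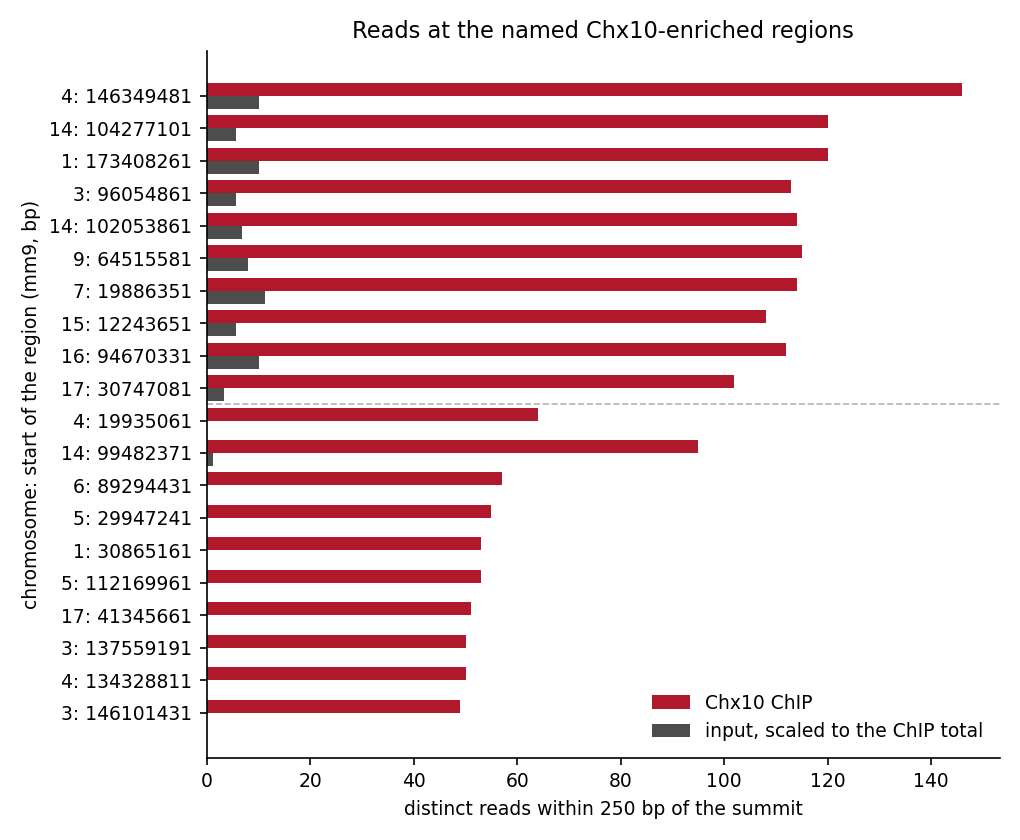
Distinct ChIP reads (red bars) and depth-scaled input reads (grey bars) within 250 bp of the summit at the 20 named regions, listed by chromosome and mm9 start position; the dashed line parts the 10 regions with the highest ChIP minus input from the 10 with the highest lower bound of the ratio. ChIP reads range from 49 to 146, and 9 of the lower 10 regions had 0 input reads.

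The second comparison asked how the regions were spread over the genome. Relative to its share of well-placed input reads, chromosome 11 carried the most Chx10 regions, 1049 against 889 expected (ratio 1.18, 1.11 to 1.254). Chromosome 17 had 1.14 times (1.06 to 1.23) and chromosome 19 had 1.12 times (1.02 to 1.23) the expected number. Fewer regions than expected lay on chromosome 16 (0.878, 0.807 to 0.953), chromosome 3 (0.887, 0.830 to 0.947) and chromosome 1 (0.896, 0.845 to 0.949). Without places of high input, these 6 chromosomes kept intervals on the same side of 1, the nearest being 1.03 to 1.24 on chromosome 19. Expected numbers rise in proportion to reads, but regions fell from 17025 to 6681 with both libraries thinned to 50%. Input density was 1.11 of the autosomal median on chromosome 11, 1.06 on 19, 0.943 on 3 and 0.958 on 1. These lie on the same side of 1 as their ratios, as does 0.985 on 16, but 0.988 on 17 does not. Depth was not matched between autosomes, and its part was not tested. Regions, unlike the expected numbers, came from reads of every mapping quality. Chromosome X stood apart with 213 regions against 467 expected, a ratio of 0.456 (0.397 to 0.522). The input density of chromosome X was itself 0.428 of the autosomal median, and a lower density leaves fewer regions detectable. With the autosomes thinned to that density, the ratio of regions per Mb was 1.05 (0.902 to 1.21). Depth was not closely matched there, since the density came from reads with a mapping quality of at least 30 and reads of every mapping quality were thinned. From reads with a mapping quality of at least 10, thinned in the same way, the ratio was 0.676 (0.549 to 0.823).

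**Figure D3:**
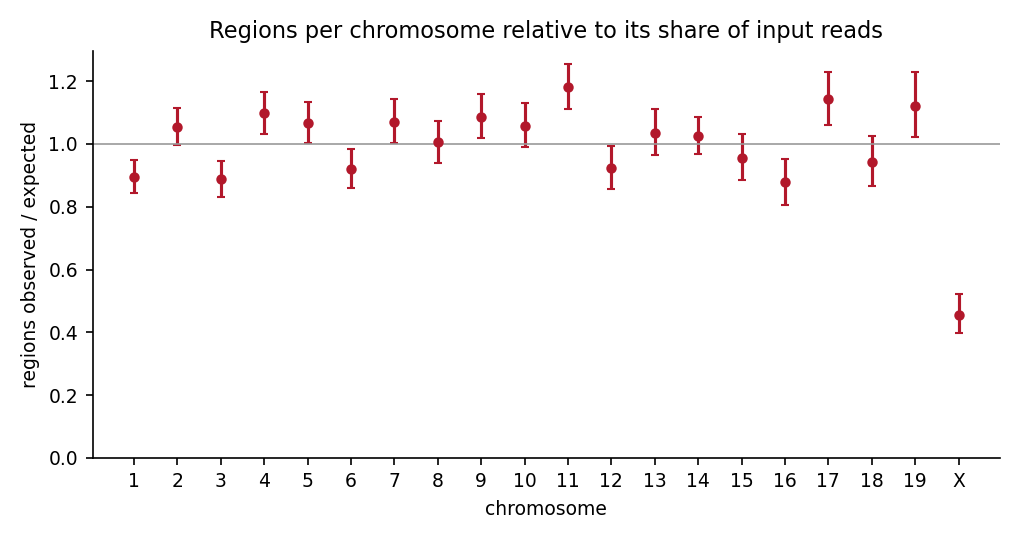
Ratio of the observed number of Chx10-enriched regions to the number expected from the chromosome's share of input reads with a mapping quality of 10 or more (vertical axis) for each chromosome (horizontal axis); bars are 95% Poisson intervals. Chromosome 11 is highest at 1.18, and chromosome X lies at 0.456.

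Chx10 regions lay closer together than random positions drawn from input reads on the same chromosomes. Another region lay within 10 kb of 20.4% of them (Wilson interval 19.8 to 20.96), against a mean of 14.2% and a highest value of 15.0% over 100 random sets. Among the 16582 regions outside chromosome Y, the mitochondrial genome and places of high input, 598 formed 189 chains of 3 or more with gaps of at most 10 kb. The chain with the most members had 6 regions over 26.9 kb of chromosome 14, from 65243501 to 65270360, with 204 ChIP and 48 input reads at the summits (median ratio 4.01), inside the segment of raised density. Chains of 5 regions lay on chromosome 9 at 114449211 to 114464560 (198 ChIP and 13 input reads, median ratio 13.9), on chromosome 7 at 29468901 to 29481710 (160 and 14, median ratio 7.998), and on chromosome 5 at 106880021 to 106894070 (130 and 9, median ratio 16.0). A further 2 chains of 5 lay on chromosome 11 at 88477591 to 88491570 (127 and 22, median ratio 5.11) and on chromosome 7 at 146600881 to 146615730 (116 and 19, median ratio 7.998), where a mean of 67.2% of the ChIP reads per region had a mapping quality of 10 or more.

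Segments of raised read density lay on chromosomes 8 and 14 in both the ChIP and the input, each followed by a segment of lowered density. Between 61.95 and 117.70 Mb of chromosome 14, the median 100-kb bin held 1.99 times the autosomal median in the input and 1.97 times in the ChIP, and beyond 117.70 Mb it held 0.527 and 0.522 times. On chromosome 8, the bins from 107.45 to 117.32 Mb stood at 1.63 times in the input and 1.72 times in the ChIP, and those from 117.32 to 121.31 Mb at 0.551 and 0.523 times. Lowered density was not particular to these chromosomes: of a similar level were chromosome 6 at 129.4 to 133.2 Mb (0.566 in the input) and chromosome 7 at 59.2 to 62.3 Mb (0.605) and 65.9 to 69.9 Mb (0.528). With reads of every mapping quality, these 3 came to 0.867, 0.788 and 0.761, and the lowered segments of chromosomes 14 and 8 to 0.544 and 0.515. Outside chromosome Y, the mitochondrial genome and places of high input, the raised segment of chromosome 14 held 621 Chx10 regions, or 11.2 per Mb against 6.76 on the autosomes other than 8 and 14 (1.65 times, 1.52 to 1.79). Their median ratio was 5.63 (bootstrap interval 5.33 to 5.92), below the 7.55 of those autosomes. The genome-wide rate set the same minimum pileup of 7 reads at both densities, but higher local input rates raised the pileup needed in the segment. These medians therefore do not compare like sites. With the reads of the segment thinned to 50% in both libraries, 265 regions were left there, 0.704 times (0.621 to 0.795) the regions per Mb of those autosomes.

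**Figure D4:**
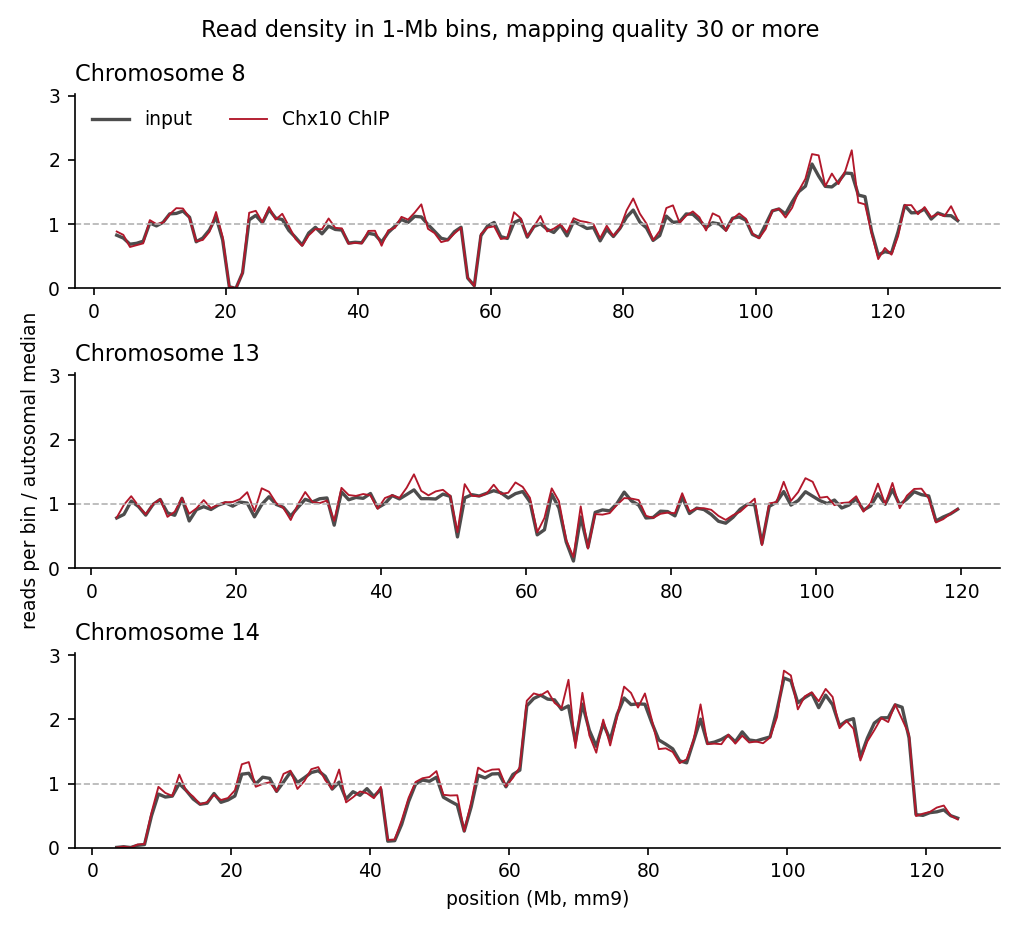
Read density in 1-Mb bins relative to the autosomal median (vertical axis) along chromosomes 8, 13 and 14 (horizontal axis, Mb of mm9) for the input (grey) and the ChIP (red), from distinct reads with a mapping quality of 30 or more; the dashed line marks the autosomal median. Both libraries rise on chromosome 14 at 61.95 Mb and fall at 117.70 Mb, while chromosome 13, shown for comparison, has a median of 0.997 in the input.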

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

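All tests below were chosen after the data were seen. For the thinnings, the lowered segments and the gapped alignments, the bounds were written before the result of the test itself; for the other tests, and for leaving out 1 input-only locus, the values were already known. No biological explanation by group was tested, since each group has 1 library.

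The input, which serves only as background in the comparisons, showed a signal of its own: a median density of 1.99 between 61.95 and 117.70 Mb of chromosome 14 and of 1.63 in the raised segment of chromosome 8, relative to the autosomal median. For the lowered segments, the tables argue against mappability or the filter on mapping quality, since reads of every mapping quality still gave medians of 0.544 and 0.515. In the raised segments, such reads gave medians of 1.985 (lower quartile 1.71) and 1.52 (1.44). That is no separate test, because they include the reads by which these segments were picked and could not have fallen to the bound set for this explanation. The tables also argue against the preparation of 1 library, since the ChIP to input ratio between the chromosome 14 steps was 0.968 (0.964 to 0.973). Both chromosome 14 steps fell at the same 10-kb position in the 2 libraries (on chromosome 8, the rise lay at 107.45 Mb in the input and 107.58 Mb in the ChIP). Collapsed repeats of the build are not excluded, as the raised segments were picked by a density of at least 1.5, and a change in DNA copy number in the cells stays open as a hypothesis: the density between the steps was 1.97 times that before the first (quartiles 1.66 to 2.22), and 0.527 of the autosomal median after the second. Doubled read density may also account for the higher number of Chx10 regions there, because thinning the segment took the regions per Mb from 1.65 to 0.704 times those of other autosomes. The interval after thinning (0.621 to 0.795) lay below 1, so the thinned segment had fewer regions per Mb than those autosomes. The cause of that deficit was not tested, and it rests on 1 random thinning.

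Chromosome X carried fewer Chx10 regions than its input reads predict, and read depth was weighed as the reason. A first test, with both libraries thinned, left X at 0.485 (0.418 to 0.559) of the autosomes, a value that had been set in advance to exclude depth; that bound was wrong, because thinning also took the genome-wide rate from 0.648 to 0.338 reads per fragment length for the autosomes and not for X. With the rate kept and the autosomes thinned to the density of X, the ratio was 1.05 (0.902 to 1.21). This met the bound set in advance for a depth effect, but the test was not closely matched. The density came from reads with a mapping quality of at least 30 and was used to thin reads of every mapping quality. The autosomes may have been thinned too far, which would raise the ratio, so no conclusion is drawn from it. From reads with a mapping quality of at least 10, however, the same ratio was 0.676 (0.549 to 0.823): it reaches the 0.8 set in advance for a depth effect but not 1, because 104 regions remained on X against 195 from all reads. Without thinning, the ratio from these reads was 0.114 (0.0934 to 0.139). Depth may therefore account for much of the deficit among them. Whether a remainder exists among well-placed reads stays open, since it rests on 104 regions and 1 random thinning.

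Of the regions called in the exchanged libraries, 5 had at least 20 distinct input reads by fragment centre and 0 ChIP reads; counted by read start with every copy, the input reads were 106 on chromosome 16 at 86821001 to 86821520, 81 on chromosome 5 at 37051981 to 37052350, 26 on chromosome 1 at 85328841 to 85329010, 20 on chromosome Y at 2788401 to 2788690 and 15 on chromosome 4 at 145569421 to 145569620. PCR copies of a few fragments were left out by this choice of loci, so the share of distinct starts, 84.6% or more at each locus, is no separate test of them. The mapping quality was low, with a highest median of 6 over the loci, which DNA of another source in the input that aligns there imperfectly may explain, but reads that match several places would have it too, and neither mismatches nor multiple placement were measured. Of the plus-strand reads, 19.8% (12.4 to 29.2, exact binomial) spanned a length other than that of the read, against 10.8% in the whole input. Whether gapped alignments play a part stays open, because 11 of these 19 reads lay on chromosome 16, without which the share was 16.7% (7.48 to 30.2), and the other loci differed: 4 of 9 on chromosome Y, 4 of 25 on chromosome 5, 0 of 6 on chromosome 1 and 0 of 8 on chromosome 4.

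The densest 6 windows of 10 kb held 8.84% of all ChIP reads against 5.74% of the input reads, counting every copy, and 4.88% against 3.14% lay in a single one on chromosome 2 at 98500001 to 98510000. In that window, only 3437 of 688788 ChIP reads and 2928 of 356999 input reads were distinct.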

How the results depend on the processing

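Mapping quality, the split of both libraries, the thinnings other than to the smaller library and the ChIP parts, the chromosome 14 settings, the 100-kb neighbours and the exchanged libraries without Y, the mitochondrial genome and high-input places were added after the data were seen. The number of Chx10 regions stayed within 1.5 times of 17025 in 9 settings, from 12571 with a ratio of at least 5 to 19717 with the input scaled by background bins. Some of these settings only filtered the same calls: the ratio of at least 5, leaving out Y, the mitochondrial genome and high-input places, and leaving out the chromosome 14 segment. Among those called anew, the lowest number was 12667, with libraries thinned to the smaller one. The number moved to 26248 with the genome-wide rate only, of which 16948 overlapped the regions reported, and to 6723 at 1e-08. Fewer reads gave fewer regions by construction: 11158 with 75% of the ChIP reads, 6979 and 6874 in random parts of 50% (4078 shared by any overlap, 4040 by 50% of the shorter), 2543 with 25%, 6681 with both libraries thinned to 50%, 5753 in the first part of the distinct reads of both, 4866 with the autosomes thinned to the density of X and 3918 with that and mapping quality of at least 10. Depth therefore limits how many sites can be listed. Exchanged libraries gave 595 regions with all copies kept, 100 at 1e-08, 91 at mapping quality of at least 10 and 102 without Y, the mitochondrial genome and high-input places, and 171 with background-bin scaling. The median ratio was 11.6 within 100 bp, 4.89 within 500 bp, 8.94 with background-bin scaling and 7.80 at mapping quality of at least 10. Neighbours within 10 kb fell to 11.8% at 1e-08 (random mean 6.28%) and 18.5% at mapping quality of at least 10 (12.3%), and 78.5% had one within 100 kb (75.1%). The cause was not tested for the last 3 groups.

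The 20 named regions were called in 375 of 380 pairs of region and setting, each in at least 18 of 19 settings. They were picked for high enrichment in the same reads, and some settings leave their counts unchanged, so this is no independent check. No paired analysis was possible because each group has 1 library. Alternatives on promoter distance, gene lists and motifs were not run, since no genome or annotation of mm9 was used here.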

Other observations

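The libraries differed in their shares of mitochondrial and chromosome Y reads. Mitochondrial reads were 0.0187% of the ChIP and 0.0812% of the input, a ratio of 0.230 (0.220 to 0.240), and chromosome Y reads stood at 0.597 (0.560 to 0.636) of the input share. Among the densest windows, the one on chromosome 6 at 103590001 to 103600000 had the highest ratio of all reads, 34375 in the ChIP against 6836 in the input (4.05, 3.95 to 4.16), although only 313 and 261 of them were distinct. Chromosome 4 held a chain of 4 regions at 146127201 to 146143840, near the region with the most Chx10 reads over input, in which a mean of 15.8% of the ChIP reads per region had a mapping quality of 10 or more.

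Outside places of high input, the 195 regions on chromosome X had a median ratio of 8.89 (bootstrap interval 7.55 to 11.6), and those of the autosomes other than 8 and 14 one of 7.55. All 213 regions on X had a median of 7.998. The minimum pileup set by the genome-wide rate, 7 reads, was the same on X, where input density was 0.428 of the autosomal median. These medians therefore do not compare like sites. Of all 17025 regions, 13750 (80.8%) overlapped a region called from reads with a mapping quality of at least 10.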
